A study of Arabidopsis thaliana with 6 samples.

How the data were processed

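FUL binding was measured by ChIP-seq with a GFP-tagged FUL protein in inflorescence meristems (IM) and in pistils. Per the labels, each tissue had 2 biological ChIP replicates and 1 input library as a control, 6 samples in all, from plants grown at 21 °C with 16 h of light and 8 h of dark. Tissue was fixed for 15 to 30 min, libraries were made with the ThruPLEX kit, and sequencing was on an Illumina HiSeq. Groups were taken from the labels, which give the tissue and whether an antibody was used. IM plants carried 35S:AP1-GR, ap1-1 and cal-1, and pistil plants carried ful-1, so tissue and mutant background cannot be separated in these data.

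The submitters' processing notes name Bowtie 1.1.2, Picard 2.60, MACS2 2.1.0, deepTools and the genome build TAIR10, without role or order. The authors deposited 1 peak list per tissue in narrowPeak layout. Its fold enrichment is a ratio at the summit of the peak, as deposited by the authors. Its −log10 p and −log10 q values at the summit and its score, which equals 10 times the −log10 p cut to a whole number, are also the authors' deposited values. Peak names in the deposited lists contain the word pooled, so peaks were called on the replicates together. Peak numbers have gaps, so each list is a selection from a longer one. The rule of that selection, the caller's settings, the treatment of the input library and of duplicate reads are not given in the sources used here. A selection on agreement between replicates, on p or on fold would each remove different weak peaks, so the absence of a peak from a list does not show absence of binding. The lists ended at different −log10 p values. Folds were used to describe, rank and filter peaks within their own list. Exceptions were the choice of gene list members to name and 1 comparison of −log10 p at like fold. Read depth per sample is unknown from these lists, and no error across replicates could be computed. Signal tracks and reads were not analysed here.

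Gene names and positions came from a table of RefSeq genes of assembly TAIR10.1, restricted to 27444 protein-coding genes on 5 chromosomes. Because the deposited build is named TAIR10, none of the table's coordinates are printed, and its register with the peaks was tested. The share of summits inside genes was 29.5% for IM and 26.0% for pistil in place, and between 60.2% and 65.0% (IM) or 56.3% and 63.1% (pistil) when summits were moved by 2 kb or more, in steps of 500 bp up to 10 kb. It was lowest in place on all 5 chromosomes for both lists. Distances to genes rest on this. The table holds no strand and no exons, and no genome sequence was used here. The planned classes of promoter, untranslated region, coding sequence and intron were therefore replaced by position inside a protein-coding gene, within 1 kb, from 1 to 3 kb and beyond 3 kb of one. The planned window of 3 kb upstream to 1 kb downstream became 3 kb on either side of a gene, and the planned narrower window and nearest start became 1 kb on either side and the gene nearest to each summit within 3 kb. The planned tests of CArG boxes and other motifs under summits were not run.

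Peaks were called shared when they overlapped a peak of the other list by at least 1 bp. Shares are given with Wilson 95% intervals, which cover counting error only, and were compared with 1000 random placements of peaks of the same widths, with a one-sided permutation p. Chromosome lengths for these placements were taken as the end of the last gene or peak. Within each list, the median log2 fold of shared and other peaks was compared by a two-sided permutation test with 100000 resamples, with a bootstrap interval of the difference. Position classes were compared between tissues by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 4 classes.

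Gene lists were fixed before the data were examined: 30 lists, among them 5 controls (reference genes, seed storage genes, root genes, ribosomal proteins and photosystem genes). Lists of named genes held 228 names, of which 1 did not match the table and 2 were second names of a gene already in their list, which left 225. FUL, SOC1, RGA, SEP1 and SEP2 were matched through a locus given by hand. Families were gathered by a pattern on symbols and synonyms, so some hold other genes: the ribosomal pattern takes RPS disease resistance genes, the Aux/IAA pattern takes MP, ARF19 and NPH4, and GRF covers growth-regulating factors and 14-3-3 proteins. The homeobox pattern takes the haemoglobin genes AT2G16060 and AT3G10520, the ARF pattern the ADP-ribosylation factor genes AT1G23490 and AT2G24765, and the SPL pattern the SP1-like genes AT1G54150 and AT1G59560; of these 6, AT1G54150 was a target, in IM only. The photosystem pattern takes PSAT genes. The tests were not repeated without them. A pattern also misses members named in other ways, so its counts cover the matched genes and not a whole family. List members among targets were tested against all other protein-coding genes by Fisher's exact test, two-sided, adjusted over 60 tests. The tissue difference compared members targeted in IM only and in pistil only with the same counts for all other genes, adjusted over 30 lists. An adjusted p under 0.05 passed.

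The text names 30 genes fixed beforehand, the 5 peaks with the highest fold of each list, the 5 with the highest fold among peaks of 1 tissue, and up to 4 members of each gene list with the highest fold in either tissue. A gene is given by its peak of highest fold within 3 kb, so its folds in IM and pistil can come from different sites. This is stated where the peaks did not overlap. Such a peak can still overlap another peak of the other list, as both did at AG, GA20OX1, TCP9, GRF3 and WRKY2. Other genes named for a count of few members were chosen after their values were seen. The values of 1 gene and 1 gene list are not reported here.

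Alternatives fixed beforehand were other rules for shared peaks (50% of both peaks, summits within 100 bp), stricter thresholds (folds above the list's median, the 1000 highest folds), placements near genes, −log10 q in place of fold, the middle of a peak in place of its summit, other gene windows, and 10000 random gene lists matched on flank length in 20 bins. Chosen after seeing the data were circular shifts of all summits by at least 50 kb (1000 draws), placements outside genes, and a common threshold at the lowest −log10 p of the pistil list. The programs were tested on simulated data. All planted overlaps were found (100% of those made from the IM list of 3650 peaks). Over 27444 genes, lists of 20 members with no enrichment had an unadjusted p under 0.05 in 5.5% of 200 simulations, and lists with an odds ratio of 3 in 72% (20 members) or 99% (80 members). Genes were drawn independently and at 1 common rate in these simulations. They therefore do not show the rate of false passes where neighbouring genes share a summit or flanks differ in length. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with a random seed of 1.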

Results

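Binding of FRUITFULL (FUL), a MADS-domain transcription factor of Arabidopsis thaliana known for its part in the floral transition and in fruit development, was mapped by ChIP-seq in 2 tissues. A GFP-tagged FUL protein expressed from the FUL promoter was precipitated with anti-GFP beads. Inflorescence meristems (IM) came from plants aged 4 to 5 weeks that carried the ap1-1 and cal-1 mutations, in which the shoot apex keeps forming meristems in place of flowers, and an AP1-GR transgene that had not been induced. Pistils of stages 12 to 16 came from plants with the ful-1 mutation. Each tissue had 2 ChIP replicates and 1 input library, 6 samples in all. The values analysed were 1 list of peaks per tissue, called on the replicates together, so no spread between replicates could be measured. The read depth behind the peaks is unknown, intervals on shares cover counting error only, and p-values describe the lists rather than plants. Tissue and mutant background also differed together. Coordinates are on TAIR10, and each fold enrichment is the authors' value at the summit of a peak, compared within its own list unless stated.

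The strongest sites of both tissues lay next to genes of several kinds, with regulators of flowering among them. In the IM list the highest fold, 9.81, belonged to a peak on chromosome 3 (3097638 to 3099072) whose summit lay inside AT3G10040, followed by a peak 101 bp from HAC5, a histone acetyltransferase gene (fold 9.75), and a peak inside AGL18, a MADS-box gene that delays flowering (fold 9.63, chromosome 3, 21232960 to 21234577). In the pistil list the highest fold, 15.3, was 244 bp from ATG18C, an autophagy gene (chromosome 2, 17031398 to 17032859), and the same site had rank 4 in the IM list with a fold of 9.32. The floral homeotic gene AP2 had the next pistil peak, with its summit 1611 bp from the gene (fold 15.1, chromosome 4, 17397006 to 17399748). A neighbouring peak 2353 bp from LEJ2 had a fold of 15.0, a peak 132 bp from AT1G11560 one of 14.9, and a peak on chromosome 2 (15940874 to 15941905) with no protein-coding gene within 3 kb one of 14.6. The fifth IM peak lay inside AT5G58900 (fold 9.19).

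The IM list held 3650 peaks with a median width of 1075.5 bp (quartiles 845 to 1538 bp) and a median fold of 3.77 (3.22 to 4.68). The pistil list held 3494 peaks with a median width of 904 bp (695 to 1266 bp) and a median fold of 4.10 (3.41 to 5.63). Peaks covered 3.95% of the chromosomes in the IM list and 3.12% in the pistil list. The lowest −log10 p was 22.4 in the IM list and 34.4 in the pistil list, so the lists ended at different limits. Peak numbers in both lists had gaps, with 3650 peaks listed up to number 13754 for IM and 3494 up to number 14602 for pistil.

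The first comparison asked which sites were bound in both tissues. Peaks near SOC1, AP2, TOE3, SHP2, SEP3 and AGL18 were found in both lists. By contrast, a pistil peak 169 bp from SAUR29, a gene of the auxin-responsive SAUR family, had no partner in the IM list (fold 13.2, chromosome 3, 977174 to 977972), nor had peaks inside AT1G35780 (fold 12.6), 2613 bp from AT2G27775 (12.5), inside RFR1 (12.5) and inside AT2G30230 (12.3). The highest folds among peaks found in the IM list only were inside LSH2 (7.57, chromosome 3, 1216129 to 1217460), inside the cytokinin synthesis gene IPT5 (7.45, chromosome 5, 6361235 to 6362448), 153 bp from AT5G59390 (7.34), inside MLO6 (7.06) and inside LARP1b (6.99).

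Of the IM peaks, 2170 of 3650 overlapped a pistil peak by at least 1 bp (59.5%, Wilson 95% interval 57.9 to 61.0%), which left 1480 found in IM only. Of the pistil peaks, 2216 of 3494 overlapped an IM peak (63.4%, 61.8 to 65.0%), which left 1278. Randomly placed peaks of the same widths overlapped in 6.65% of IM peaks and 7.04% of pistil peaks on average (one-sided permutation p = 0.001 for each list, the smallest that 1000 placements can give). Placed only outside genes and within 3 kb of one, they overlapped in 11.3% and 11.5%, with the same permutation p. The share rose with fold. In the tenth of IM peaks with the lowest folds 40.3% (35.4 to 45.4%) had a partner, and in the tenth with the highest 94.8% (92.0 to 96.6%). For pistil peaks these shares were 42.6% (37.5 to 47.8%) and 85.7% (81.7 to 89.0%). Among the peaks with the highest folds, 19 of 365 in IM and 50 of 350 in pistil were found in 1 list only.

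**Figure D1:**
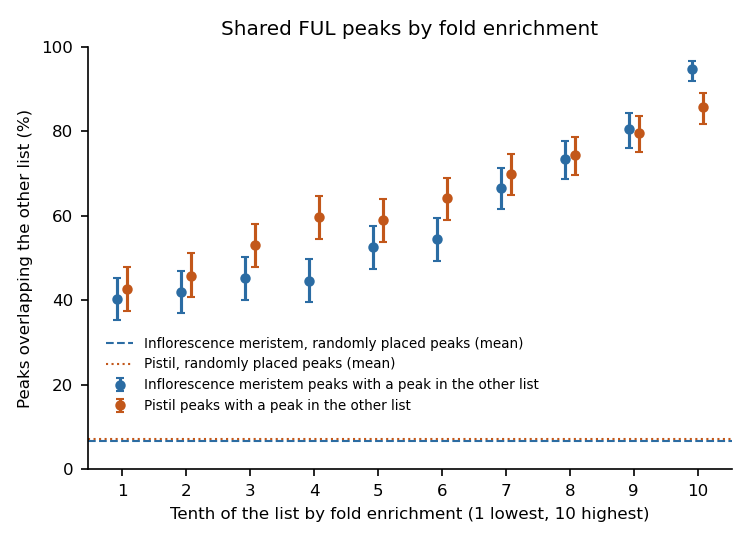
Share of peaks that overlap a peak of the other tissue (y axis, percent) in 10 equal parts of the list ordered by fold enrichment (x axis), for the IM list (blue) and the pistil list (orange); bars are Wilson 95% intervals and horizontal lines the mean of 1000 random placements of the whole list. The IM share goes from 40.3% to 94.8% and the pistil share from 42.6% to 85.7%, against 6.65% and 7.04% at random.

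Peaks shared by the tissues, such as those at SOC1 and AP2, had higher folds than peaks of 1 tissue within the same list. In the IM list the median fold was 4.16 for shared peaks and 3.43 for IM-only peaks, a log2 difference of 0.28 (bootstrap 95% interval 0.25 to 0.31). In the pistil list the medians were 4.53 and 3.67, a log2 difference of 0.31 (0.26 to 0.35). Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give.

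Summits lay beside genes more often than in them. The summits at SHP2 (265 bp away in IM, 272 bp in pistil) and ATH1 (76 and 37 bp) stood just outside the gene, those at AP2 and TOE3 between 1 and 3 kb away, and those at LFY, AGL18 and SPL2 inside it. Inside protein-coding genes lay 29.5% of IM summits (28.0 to 31.0%) and 26.0% of pistil summits (24.6 to 27.5%), against 54.1% of randomly placed ones. Within 1 kb of a gene lay 50.7% of IM and 49.2% of pistil summits, against 20.4% at random. The lists differed in 3 of the 4 position classes, by tests that count a site shared by the lists in each of them as if independent. IM summits were inside genes more often than pistil summits (odds ratio 1.19, Fisher's exact test, two-sided, adjusted exact p = 0.0014). They were less often 1 to 3 kb away (16.4% against 19.6%, adjusted exact p = 0.0011) and less often over 3 kb away (3.34% against 5.24%, adjusted exact p = 0.00033). The class within 1 kb did not pass the test (adjusted exact p = 0.19). The shared and 1-tissue peaks also differed in opposite ways. Summits were inside genes for 27.8% of shared and 32.0% of IM-only peaks in the IM list (odds ratio 0.82, Fisher's exact p = 0.0062), and for 27.3% of shared and 23.7% of pistil-only peaks in the pistil list (odds ratio 1.21, p = 0.018). The gap inside genes thus lay mainly in peaks of 1 list. Which peaks those are depends on where each list ended, and position was not tested at a common threshold on p. Strand and exons were not used here, so promoters, untranslated regions and introns are not told apart.

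**Figure D2:**
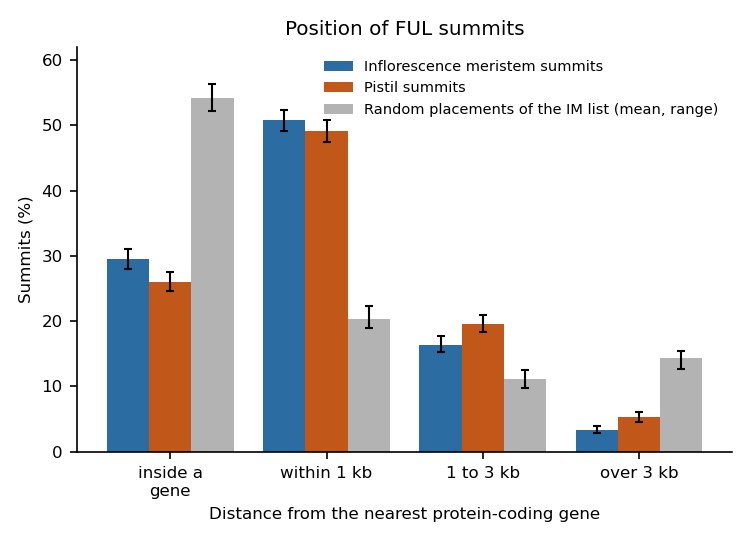
Share of summits (y axis, percent) by distance from the nearest protein-coding gene (x axis) for the IM list (blue), the pistil list (orange) and random placements of the IM list (grey); bars are Wilson 95% intervals, for grey the range of the placements. Inside genes lie 29.5% and 26.0% of summits against 54.1% at random.

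A gene was counted as a target when a summit lay inside it or within 3 kb of either end, which does not show that the gene is regulated. Another gene can lie nearer to the summit. Of the targets named below, GA2OX1, BZR1, YUC1, LOG8, CKX6, SNZ, PI and SPL5 were not the nearest gene to any summit in either list. SOC1, SVP, SEP3, AG, LFY, TFL1, AP2, TOE3, SHP1 and SHP2 were targets in both tissues. WUS and STM, which keep the shoot meristem active, were targets in IM only, while AP1 and IND, which specify floral meristems and valve margins, were targets in pistil only. The WUS peak had a −log10 q of 22.9, below the lowest of the pistil list (32.5). In all, 6505 of 27444 protein-coding genes were targets in IM (23.7%) and 5859 in pistil (21.3%). Both tissues shared 4210 targets, where independent lists would share 1389 (odds ratio 21.5, Fisher's exact test), which left 2295 genes in IM only and 1649 in pistil only. The window and the limits of the lists set these counts. With 1 threshold on p for both lists, the lowest of the pistil list, which removes IM peaks only, 4432 IM genes were targets, and 1134 genes were IM-only and 2561 pistil-only, so the tissue with more targets changed. With the gene nearest to each summit alone, 3210 IM genes and 2958 pistil genes were targets, 1944 of them in both.

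The next comparison asked which groups of regulatory genes lay near FUL summits in each tissue. Among the 22 floral MADS-box genes, 16 were targets in IM and 15 in pistil, and 14 were targets in both, including SOC1, SEP3, AG and SHP2 and also SEP1, SEP2, AP3 and PI. Of the 6 AP2-like genes, which repress flowering or pattern the flower, AP2, TOE1, TOE3, SMZ and SNZ were targets in both tissues. Their highest folds in the pistil list were 15.1 at AP2, 14.2 at TOE3, 9.72 at SMZ, 8.29 at TOE1 and 6.28 at SNZ, and in the IM list they lay between 6.06 at SNZ and 7.94 at TOE3. Of 19 shoot meristem and boundary genes, 15 were targets in IM and 9 in pistil, among them ATH1 (fold 7.27 in IM, 9.38 in pistil), HB51 (4.56 and 9.57) and BLH9 (3.39 and 7.56). Among 22 flowering time genes 13 were targets in each tissue, among them FD (8.64 in IM, 6.03 in pistil), FLC (8.04 and 5.30), ATC (7.20 and 12.6) and BFT (3.11 and 9.73). These were chosen by the higher of their IM and pistil folds and do not lead in each list.

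These shares were above those of all other genes in both tissues. The odds ratios in IM and pistil were 8.60 (Fisher's exact test, two-sided, adjusted exact p = 3.2e-05) and 7.91 (4.0e-05) for the floral MADS-box genes and 12.1 (1.8e-05) and 3.32 (0.020) for the meristem genes. They were 16.1 (0.0080) and 18.4 (0.0060) for the AP2-like genes and 4.66 (0.0017) and 5.33 (0.00079) for flowering time. Of 23 genes of gynoecium and valve margin patterning, 13 were targets in IM (odds ratio 4.19, adjusted exact p = 0.0025) and 11 in pistil (3.38, adjusted exact p = 0.0092). They included SHP2 (fold 8.14 in IM and 12.2 in pistil), ADPG2 (6.18 and 10.2), JAG (4.48 and 9.54, at different sites) and ETT (8.91 and 9.54). Against random genes matched on the length of their flanks, the pistil result did not pass for the fruit genes (adjusted permutation p = 0.092) or the meristem genes (adjusted permutation p = 0.12).

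Hormone genes were targets in both tissues. Of 24 genes of auxin synthesis, transport and response, 14 were targets in IM (odds ratio 4.51, adjusted exact p = 0.0013) and 15 in pistil (6.15, adjusted exact p = 0.00013), among them GH3.3 (fold 5.20 and 9.36), the kinase gene PID (3.39 and 8.31) and YUC1 (4.46 and 7.56). Of 18 brassinosteroid genes, 10 were targets in IM (4.03, adjusted exact p = 0.0080) and 13 in pistil (9.60, adjusted exact p = 5.4e-05), with the receptor gene BRI1 at 6.41 and 10.3, BZR1 at 7.33 and 9.19, BEE3 at 5.57 and 7.33 and BES1 at 3.93 and 6.41. Of 21 gibberellin genes, 14 were targets in IM (6.45, adjusted exact p = 0.00027) and 11 in pistil (4.06, adjusted exact p = 0.0050). They included the catabolic gene GA2OX1 (6.84 and 12.0), the synthesis gene GA20OX1 (5.39 and 10.6, at different sites), GA2OX8 (4.52 and 7.75) and the receptor gene GID1B (6.02 and 6.20). Of 25 cytokinin genes, 12 were targets in each tissue (2.97, adjusted exact p = 0.017, and 3.41, adjusted exact p = 0.0066), with LOG8 at 5.04 and 11.8, LOG1 at 6.81 and 9.49, CKX6 at 5.31 and 9.15 and ARR4 at 5.47 and 8.25. With folds above the list's median, the auxin result in IM did not pass (odds ratio 2.24, adjusted exact p = 0.19).

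Families gathered by symbol are given with the odds ratios for IM and then pistil, and genes with their folds in the same order. Of 32 Aux/IAA symbols, which by synonym include MP, ARF19 and NPH4, 17 were targets in IM (odds ratio 3.66, adjusted exact p = 0.0018) and 19 in pistil (5.40, adjusted exact p = 4.0e-05), with ATAUX2-11 at 5.45 and 13.2 and IAA12 and IAA19 in pistil only (10.004 and 7.27). Genes with homeobox (HB) symbols were targets in 22 of 47 cases in each tissue (2.84, adjusted exact p = 0.0018, and 3.25, adjusted exact p = 0.00068), led by HB33 (5.38 and 12.7) and HB23 (5.02 and 10.5). Of 26 genes with ERF symbols 14 were targets in each tissue (3.76, adjusted exact p = 0.0029, and 4.31, adjusted exact p = 0.0013), with ERF38 at 7.25 and 5.52, ERF7 at 6.77 and 3.61, ERF15 at 5.00 and 6.72 and ERF2 at 3.29 and 6.43. TCP genes were targets in 12 and 11 of 22 cases (3.87, adjusted exact p = 0.0050, and 3.69, adjusted exact p = 0.0066), among them the branching repressor BRC1 (5.00 and 10.1), TCP20 (5.77 and 8.31), TCP9 (4.43 and 6.40, at different sites) and TCP4 (7.49, pistil only). Genes with numbered bHLH symbols, a part of that family, were targets in 11 of 22 cases in each (3.22, adjusted exact p = 0.018, and 3.69, adjusted exact p = 0.0066), with AT1G72210 at 4.65 and 12.2, BHLH32 at 4.34 and 9.43, bHLH093 at 4.80 and 5.55 and BNQ2 at 5.55 in pistil only. SPL symbols were targets in 9 and 10 of 18 cases (3.22, adjusted exact p = 0.038, and 4.61, adjusted exact p = 0.0049), with SPL2 at 5.73 and 10.7, SPL5 at 5.70 and 6.99, SPL1 at 2.93 and 5.65 and SPL11 at 7.86 in pistil only. Against genes matched on flank length, the IM result did not pass for SPL (adjusted permutation p = 0.077) or bHLH genes (adjusted permutation p = 0.052). With folds above the list's median it did not pass for Aux/IAA (adjusted exact p = 0.11), TCP (0.28) or SPL (0.37), within 1 kb for homeobox (0.14) or TCP (0.17), at 1 threshold on p for both lists for TCP (0.11), or by the nearest gene for bHLH (0.052). The pistil result for bHLH did not pass within 1 kb (adjusted exact p = 0.073) or by the nearest gene (0.11).

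For NAC and MYB genes the test passed in 1 tissue each. NAC genes were targets in 34 of 100 cases in IM (odds ratio 1.66, adjusted exact p = 0.033) and 29 in pistil (1.51, adjusted exact p = 0.10), with NAC014 at 7.46 and 10.8, NAC3 at 6.53 and 10.8, and VND1 (8.40) and XND1 (8.21) in pistil only. MYB genes were targets in 38 of 125 cases in IM (1.41, adjusted exact p = 0.13) and 45 in pistil (2.08, adjusted exact p = 0.00091), with MYB43 at 9.50 in pistil only, MYB21 at 3.94 and 9.50, MYB90 at 5.75 and 8.89 and MYB95 at 4.00 and 8.79. The NAC result in IM ended against genes matched on flank length (adjusted permutation p = 0.16), with summits within 1 kb (adjusted exact p = 0.65), with folds above the list's median (0.094) and with 1 threshold on p for both lists (0.073). The MYB result in pistil ended within 1 kb (adjusted exact p = 0.092), while MYB genes passed in IM with the gene nearest to each summit alone (0.038). The tissue difference did not pass for either family (adjusted exact p = 1 for NAC and 0.44 for MYB).

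With the window of 3 kb, the ARF, LBD, GRF, WRKY, expansin and XTH families passed in neither tissue. Values in parentheses after the counts are the adjusted p-values of Fisher's exact test for IM and pistil. ARF symbols were targets in 10 (IM) and 9 (pistil) of 25 cases (adjusted exact p = 0.098 and 0.12), with ARF17 at 3.40 and 6.91 and ARF11 at 5.95 and 4.87. LBD genes were targets in 11 and 13 of 40 cases (0.63 and 0.15), with ASL5 at 6.32 and 11.1, LBD37 at 2.95 and 5.30, and LBD10 (10.3) and LBD42 (5.27) in pistil only. GRF symbols were targets in 8 of 22 cases in each (0.26 and 0.15), with the 14-3-3 gene GRF8 at 5.98 and 6.90, GRF2 at 4.91 and 6.88 (different sites), GRF5 at 6.63 and 6.04 and GRF3 at 6.29 and 3.35 (different sites). WRKY genes were targets in 24 and 21 of 71 cases (0.085 and 0.15), with WRKY21 at 4.73 and 7.47, WRKY32 at 7.30 and 3.71, WRKY2 at 6.003 and 5.49 (different sites) and WRKY29 at 5.78 in IM only. Expansin genes were targets in 8 and 7 of 24 cases (0.39 in both), with EXPA4 at 5.20 in IM only, EXPA10 at 5.10 and 4.01, EXPA9 at 4.94 and 4.83 and EXPA18 at 4.68 in pistil only. XTH genes were targets in 12 of 33 cases in each (0.14 and 0.085), with XTH8, whose summit was also that of AT1G11560, at 3.55 and 14.9, EXGT-A3 at 6.64 and 9.73 (different sites), XTH10 at 4.00 and 7.76 and XTH28 at 5.61 and 6.10. With the gene nearest to each summit alone, ARF (adjusted exact p = 0.012 in IM and 0.0075 in pistil) and WRKY (0.0014 and 0.018) passed in both tissues, and GRF (0.038) and XTH (0.013) in pistil. Within 1 kb GRF passed in both (0.049 and 0.028).

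None of the 5 control lists passed in either tissue. Reference genes were targets in 4 (IM) and 2 (pistil) of 14 cases (adjusted exact p = 0.78 in both), the highest being TUB2 at 6.24, CYP5 at 3.39 and GAPC1 at 3.07, each in IM only, and ACT8 at 3.26 and 3.84. Seed storage and oleosin genes were targets in 2 and 1 of 11 cases (1 and 0.53), CRU2 at 5.35 in IM only and OLEO4 at 3.42 and 3.92. Root genes were targets in 5 and 6 of 20 cases (0.81 and 0.47), with SCR at 6.25 and 5.29, CASP1 at 4.44 and 5.67 and SHR at 4.30 and 4.03. Ribosomal protein symbols were targets in 9 and 6 of 56 cases (0.26 and 0.085), with RPS2, a disease resistance gene that shares the symbol pattern, at 3.50 and 6.34 (different sites), RPS15 at 5.07 and 5.54, RPL10B at 5.04 in pistil only and RPL16A at 4.85 in IM only. Photosystem and antenna genes were targets in 10 of 55 cases in each (0.48 and 0.78), with PSBY at 7.17 and 4.77, LHCB4.1 at 6.89 and 6.91, LHCB4.3 at 5.80 and 6.64 and LHCA2 at 5.61 in pistil only. In all, 17 of 30 lists passed in each tissue. Neighbouring genes can share a summit, and these tests treat genes as independent, so their p-values are too small. With summits shifted together along the chromosomes, all 17 lists of each tissue still passed. Such shifts gave fewer target genes on average, 5886 against 6505 in IM and 5496 against 5859 in pistil. That favours a pass for any list, and the lists were not tested against shorter shifts.

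**Figure D3:**
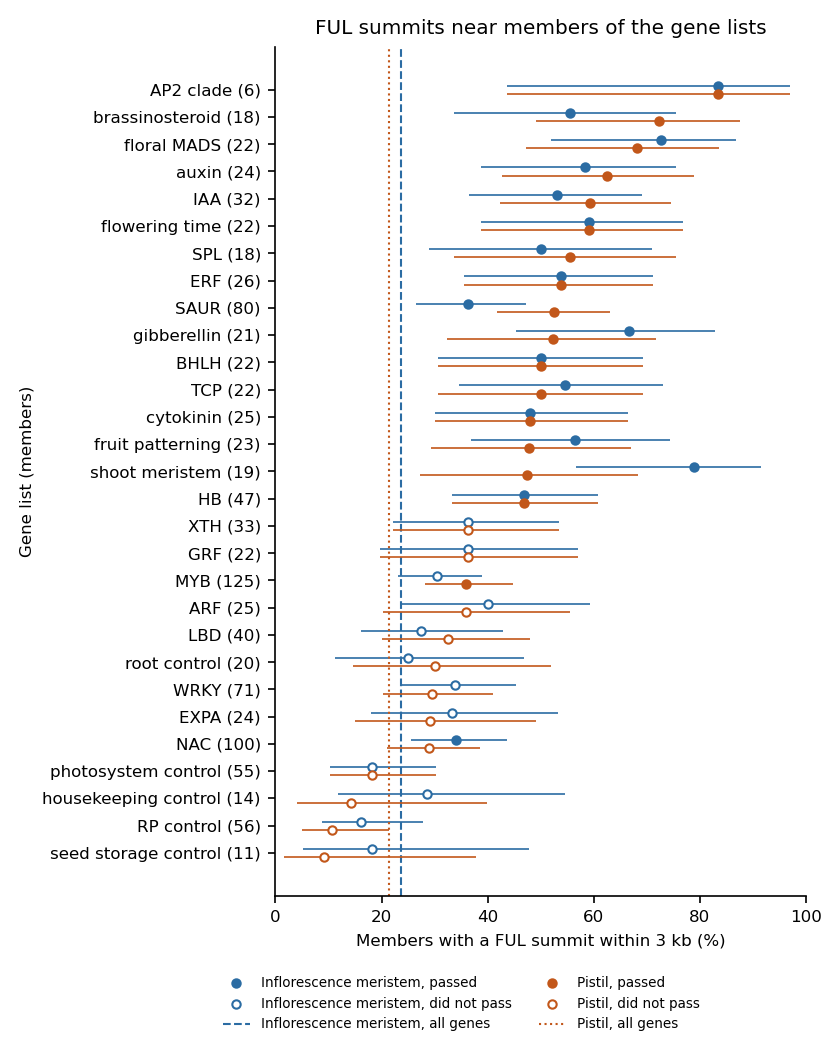
Share of the members of the gene lists described here with a FUL summit within 3 kb (x axis, percent) for IM (blue) and pistil (orange); numbers of members are in parentheses, bars are Wilson 95% intervals, filled points passed Fisher's exact test at an adjusted p under 0.05, and vertical lines give the share of all protein-coding genes. AP2-like, brassinosteroid and floral MADS-box genes lie furthest above the 23.7% and 21.3% of all genes in pistil, and the controls do not pass.

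The last comparison asked whether any gene list was targeted more in 1 tissue. The SAUR family of small auxin-responsive genes was, with 42 of 80 members targeted in pistil and 29 in IM. Of these, 26 were targets in both, 16 in pistil only, including SAUR29, SAUR28, SAUR27, SAUR26, SAUR23 and SAUR24, and 3 in IM only, which were AT2G24400, AT3G09870 and AT3G61900. SAUR10 had a summit in both lists, at 1362 bp in IM and 1254 bp in pistil. It ranked 2999th of 3650 by fold in IM (3.09, chromosome 2, 7831995 to 7832869) and 8th of 3494 in pistil (14.3, chromosome 2, 7830945 to 7833110). SAUR29 and SAUR28 shared the pistil peak with a fold of 13.2, and AT4G38840 had folds of 3.70 and 10.8. The 9 meristem genes targeted in pistil were all targets in IM too, and 6 more, WUS, STM, KNAT2, BLH8, CUC1 and CUC3, were targets in IM alone.

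Among genes targeted in exactly 1 tissue, SAUR genes were IM-only less often than other genes (odds ratio 0.134, Fisher's exact test, two-sided, adjusted exact p = 0.0065 over 30 lists). With 1 threshold on p for both lists, 1 SAUR gene was IM-only and 23 were pistil-only, and the difference no longer passed the adjustment (odds ratio 0.0974, adjusted exact p = 0.088). That threshold removes IM peaks only, so the added pistil-only genes are ones whose IM peaks were removed. The limit on p was not even at like fold. Among peaks with a fold from 3 to 4, the median −log10 p was 34.0 in IM and 48.6 in pistil. For folds from 5 to 6 it was 88.5 and 125. Whether folds of lists of unknown depth can be set side by side was not tested. No other list passed. Meristem genes had 6 IM-only and 0 pistil-only members (unadjusted exact p = 0.044, adjusted exact p = 0.44), and brassinosteroid genes had 0 and 3, which were BIN2, BKI1 and BEE2 (adjusted exact p = 0.55). Within each tissue SAUR genes were targets more often than other genes, with an odds ratio of 1.83 in IM (adjusted exact p = 0.022) and 4.09 in pistil (adjusted exact p = 5.3e-08). The IM result ended with summits within 1 kb (adjusted exact p = 0.21), with folds above the list's median (0.33), with 1 threshold on p for both lists (0.081) and against genes matched on flank length (permutation, 0.075).

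Genes with known roles in flowering, meristems and fruits were then taken one by one, whether or not they had a peak. Of these 30 genes, 26 had a summit within 3 kb in IM, 24 in pistil and 22 in both, while CAL and AGL24 had none in either list. With the gene nearest to each summit alone, 21 had a summit in IM and 22 in pistil. FUL itself was overlapped by a peak on chromosome 5 from 24501690 to 24511456 in IM (9767 bp, the widest of that list, fold 8.10) and from 24504008 to 24509103 in pistil (fold 4.68). The summit lay outside the gene in both lists, at 82 bp in IM and 2438 bp in pistil. SOC1, which integrates flowering signals, had a summit inside the gene in IM (fold 8.36, chromosome 2, 18809925 to 18815172) and 30 bp from it in pistil (fold 14.3, 18810424 to 18814959). SVP had folds of 7.40 in IM and 9.05 in pistil about 2 kb from the gene, SEP3 8.37 and 11.1 and SEP4 5.13 and 6.30. AG had 6.28 and 11.7 at different sites, each of which also overlapped a peak of the other list. AGL42 had 4.04 and 3.29 at different sites, neither of which did. LFY had folds of 4.40 and 5.54 inside the gene, and TFL1 6.19 and 5.41 at 1506 and 1469 bp.

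Among fruit genes, SHP1 had folds of 4.72 and 6.11 and SHP2 8.14 and 12.2 (chromosome 2, 17818958 to 17820665 in pistil). IND had a summit 1698 bp away in pistil only (fold 4.23, chromosome 4, 44446 to 45796), and ALC one 169 bp away in IM only (2.96, chromosome 5, 26786128 to 26786932). AP1, mutated in the IM plants, had a pistil summit 2519 bp away (4.15). In IM only, WUS had a summit at 357 bp (3.07, chromosome 2, 7810932 to 7811416), STM at 1664 bp (3.65) and SPL15 at 313 bp (3.73). KNAT1 had summits inside the gene in both lists at different sites (3.67 and 2.97), and GA3OX1 had a summit 520 bp away in IM (4.02) and another inside the gene in pistil (2.78). CKX5 had folds of 2.95 and 4.62 at 1 site about 2.2 kb away. The −log10 q values of the IM peaks at ALC (25.7) and WUS (22.9) lay below the lowest of the pistil list (32.5). Single genes were not tested, and the absence of a gene from 1 list does not show that its site was unbound there.

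**Figure D4:**
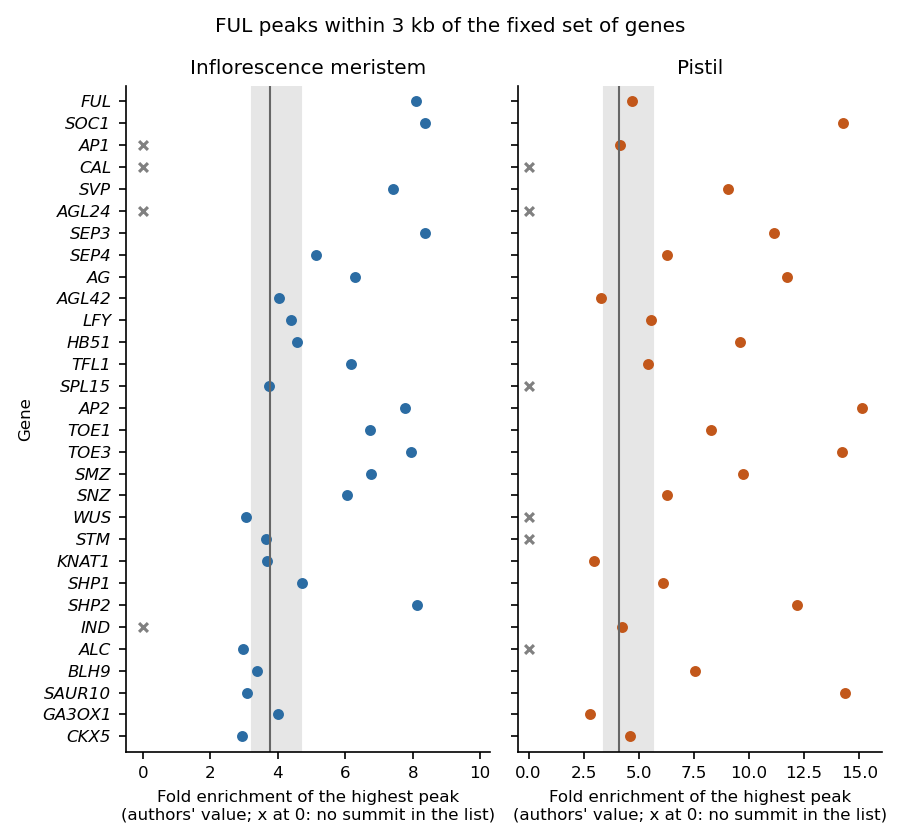
Fold enrichment (x axis, the authors' value, a separate scale per tissue) of the highest FUL peak within 3 kb of each of 30 genes (y axis), for IM (left) and pistil (right); crosses at 0 mark genes with no summit in the list, the vertical line is the list's median and the grey band its quartiles. SOC1, AP2, TOE3 and SAUR10 lie at 14.2 or above in pistil, and SAUR10 lies at 3.09 in IM, below the median of 3.77.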

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

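The tests of SAUR genes counted by peaks, of the folds of SAUR peaks and with 1 threshold on p for both lists were chosen after the result was seen.

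The SAUR genes stood out because the difference between the tissues passed its own test (adjusted Fisher's exact p = 0.00649 over 30 lists), with 16 members targeted in pistil only and 3 in IM only. Tandem SAUR genes that share 1 peak could inflate the count. Counted by peaks, however, 16 of 1278 pistil-only peaks and 2 of 1480 IM-only peaks had a SAUR gene nearest (Fisher's exact p = 0.000224), which argues against shared peaks as the whole of it. That test treats peaks as independent, so separate peaks beside neighbouring SAUR genes, such as SAUR26, SAUR27 and SAUR29, can still inflate the count. Weak pistil peaks near the limit of the list are also argued against as the whole of it. These 16 peaks had a median fold of 4.70 (3.12 to 13.2) against 3.67 for all pistil-only peaks (one-sided permutation p = 0.0066). This test too treats peaks as independent, and it rests on fold, while the rule that limits the list is unknown. Some of the 16 peaks can still be weak. A difference between the tissues stays open as a hypothesis, because with 1 threshold on p for both lists the counts were 1 and 23 but the adjusted exact p was 0.0884. That threshold removes IM peaks only and was not an even limit at like fold. The range of the adjusted exact p over the alternatives was 0.00011 to 0.088, and the mutant backgrounds differed along with the tissues.

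MicroRNA and long non-coding RNA genes, which no comparison of the report used, lay near summits more often than under circular shifts of the summits. Within 3 kb of a summit lay 73 of 326 microRNA genes in IM (22.4%, Wilson 95% interval 18.2 to 27.2%, shifted mean 16.7%) and 67 in pistil (20.6%, 16.5 to 25.3%, shifted mean 15.7%). For long non-coding RNA genes these were 842 of 3480 in IM (24.2%, shifted mean 17.5%) and 828 in pistil (23.8%, shifted mean 16.3%; one-sided permutation p = 0.001 in each, the smallest that 1000 shifts can give).

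MicroRNA genes may owe their place to the gene-rich parts of the chromosomes, which they share with the summits. The one-sided permutation p was 0.011 in IM and 0.022 in pistil with shifts of any length. With shifts of 20 to 100 kb, which stay in the same part of a chromosome, it was 0.005 and 0.05, which argues against gene-rich regions as the whole of it, narrowly in pistil. For long non-coding RNA genes the mean under these shorter shifts was 19.9% in IM and 18.4% in pistil, below the shares of 24.2% and 23.8% (one-sided permutation p = 0.001 in each). Whether a shared position between protein-coding genes gives the excess was not tested. The shares did not exceed those of protein-coding genes in IM (23.7%) or pistil (21.3%) for microRNA genes. Protein-coding genes lay below their means under the shorter shifts, which were 25.2% in IM and 23.2% in pistil, and no biological explanation was tested.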

How the results depend on the processing

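The common threshold, the placements outside genes and the circular shifts were chosen after seeing the data. The shared percentages moved with the rule but stayed above random placement under every rule tried. For IM and pistil they were 51.6% and 53.9% with 50% of both peaks and 45.5% and 47.5% with summits within 100 bp. With folds above the list's median, set against the whole other list, they were 74.0% and 74.8%. With both lists cut to their 1000 highest folds, where a partner outside the cut did not count, they were 48.3% and 48.5%. At the common p threshold the IM share was 70.2%. Inside genes lay 24.3% of pistil summits with folds above the median, and 67.2% of IM and 68.7% of pistil summits lay outside but within 3 kb. Target genes in IM, pistil and both numbered 3803, 3256 and 2187 within 1 kb, 3210, 2958 and 1944 by the nearest gene, and 3553, 3195 and 1913 with folds above the median, which follows from fewer genes or peaks being counted. At the common threshold 0 lists differed between the tissues by Fisher's exact test (1, SAUR, at an unadjusted p under 0.05), with 2346 of 3650 IM peaks left. Of 17 lists that passed in IM, matched random lists kept 13 (without bHLH, NAC, SAUR and SPL), the 1 kb window 13 (without homeobox, NAC, SAUR and TCP), the nearest gene 16 (without bHLH), folds above the median 11 (without auxin, Aux/IAA, NAC, SAUR, SPL and TCP), and the common threshold 14 (without NAC, SAUR and TCP). Of 17 in pistil, the first 4 of these kept 15 (without fruit and meristem genes), 15 (without bHLH and MYB), 16 (without bHLH) and 17; the common threshold removes no pistil peak and tests nothing there. Among the lists reported, GRF gained the call within 1 kb in both tissues, ARF and WRKY by the nearest gene in both, GRF and XTH by the nearest gene in pistil, and MYB by the nearest gene and under shifts in IM. Among 218 single list values, which leave out pistil at the common threshold, 177 kept direction and side of the threshold, 18 lost the call, 15 gained one and 8 turned, none of which passed before or after: in IM, the odds ratio became 0.478 for reference genes within 1 kb, 0.517 with folds above the median and 0.865 at the common threshold, 1.15 for seed genes at the common threshold, 0.327 for root genes within 1 kb, 0.961 for LBD with folds above the median and 1.04 for ribosomal genes within 1 kb; in pistil, 0.825 for root genes within 1 kb. The cause was not tested. No paired analysis was possible because the lists hold no values per replicate, and for the same reason no replicate could be left out. Motif alternatives were not run. Unknown depth limits which weak sites each list could hold.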

Other observations

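FUL summits stood near genes of MIR156, the microRNA that acts on SPL transcripts, and near some genes of MIR172, the microRNA that acts on the AP2-like genes. These families were chosen after the share over all microRNA genes was seen, and the difference between them was not tested. Of 10 MIR156 genes, 8 had a summit within 3 kb in both lists. MIR156a had a fold of 3.10 in IM and 8.47 in pistil, with the pistil peak on chromosome 2 from 10672951 to 10674326. MIR156e had folds of 6.05 and 7.60, MIR156f 6.67 and 6.85, MIR156d 5.67 and 6.25, and MIR156c 4.13 and 4.91. MIR156i had 3.27 and 4.13, MIR156j 3.34 and 3.43 and MIR156b 4.54 and 3.32 at different sites, while MIR156g and MIR156h had no summit. Of 5 MIR172 genes, MIR172d had a summit in IM only (fold 3.13), and MIR172a (3.13) and MIR172b (5.65, chromosome 5, 1187215 to 1187965) had summits in pistil only. Transfer RNA genes were near summits in 16.3% of 625 cases in IM and 17.9% in pistil, against means of 16.4% and 15.4% under shifts of any length and 20.6% and 21.5% under shifts of 20 to 100 kb. Pseudogenes were near summits in 2.86% and 4.26% of 3917 cases, against 21.6% and 20.1% under shifts of any length and 6.14% and 6.69% under shifts of 20 to 100 kb.

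Several genes had more than 1 FUL summit nearest to them. BRG1 had 4 in each list, bZIP44 had 3 in IM and 4 in pistil, and TOE1, XBAT31 and BXL1 had 3 in each. JAG, which acts in floral organ growth, and PID each had 2 in IM and 3 in pistil, GRF3 had 3 and 2, and MYB108 had 4 and 1. Most genes nearest to a summit had 1, which were 2918 genes in IM and 2631 in pistil. The genes named here were chosen by their counts. Each list held 1 summit per peak number, so any further summit of the same number was not counted.

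The peak over FUL was the widest of the IM list at 9767 bp, where the next widest had 6587 bp and the median was 1075.5 bp. The tests on it were chosen after its width was seen. Width could follow peak height. In pistil the peak over FUL had a fold of 4.68 and a width of 5096 bp, and its summit lay 2438 bp outside the gene (82 bp in IM). Of the 704 other peaks with a fold from 4 to 5, 1 was as wide (median 914 bp), which argues against fold alone. Peaks of like fold were not of like signal, however. The −log10 q at FUL was 237, where the −log10 p of pistil peaks in this range had a median of 83.5 (quartiles 73.9 to 93.9). Height therefore stays open in pistil. In IM the peak ranked 34th of 3650 by fold, so height stays open there, since a peak picked as the widest cannot be compared with others on width. Copies of the FUL transgene, carried by the plants of both tissues, are a candidate explanation: the pistil peak over FUL was also wide, with rank 3 of its list. Binding of FUL along its own gene would give wide peaks too, and the input libraries were not analysed here, so the transgene and binding cannot be told apart.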
